A study of Mus musculus with 12 samples.

How the data were processed

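Per the labels, RNA was extracted from tumour tissue, samples with an RNA integrity number above 7 were kept, and stranded libraries of poly(A) RNA were sequenced as read pairs in a single batch. Per the submitters' processing notes, reads were checked with FastQC, trimmed with fastp 0.23, aligned to GRCm39 with STAR 2.7.11a and counted with featureCounts of Subread 2.1.1. Per the file headers, the authors deposited raw counts of reads over exons per gene of the Ensembl 112 annotation, with no strand setting, pairs mapped at both ends required, and no option that counts a pair once. Low counts were even in 66.4% to 72.5% of cases, so most pairs add 2 counts. The command in the file headers sets no option to count reads that overlap several genes or map to several places. Since the strand was not used, reads of a gene and of an overlapping antisense gene cannot be told apart, and overlapping genes and close paralogs are uncertain.

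The totals ran from 113575859 to 156880766 counts per tumour, more than the reads per sample that the design text states, and the cause of this difference was not tested. The biological coefficient of variation between tumours of a group was 0.358. The bootstrap intervals resample genes, treat them as independent, and do not cover the spread between tumours. Of 57186 gene identifiers, 56630 were paired with a symbol and position of a GRCm39 annotation of a later release than the authors used. The column of gene lengths in the deposited table is in bases and was used only for the check of length. Within each group all pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 37.4.

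The comparison used all 12 tumours, 6 per group, and edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM scaling, filterByExpr by group, robust quasi-likelihood fits, and two-sided p-values adjusted by Benjamini-Hochberg over 19255 genes with a threshold of 0.05. Log2 fold changes are Tn over WT. The standard error is the log2 fold change divided by the root of the F statistic. CPM are TMM-scaled. The 46 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 with an estimated correlation. The level of a list in a tumour is the mean log2 CPM of its tested members with a prior count of 2, and groups were compared by an exact two-sided permutation test over all 924 assignments, adjusted over the lists. The smallest p it can give is 0.00216.

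Genes named are C1galt1c1, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 CPM and an established symbol, without immunoglobulin and T cell receptor segments, and from each list up to 4 members with the smallest p. Others are said to be chosen after their values were seen. In counts simulated from these tumours, with 19255 genes, the changed genes were drawn from those with a mean of at least 1 CPM. The test recovered 49.3% of genes changed by 1.5-fold, 71.6% at 2-fold and 97% at 4-fold, with 8 false calls. Recovery below 1 CPM was not measured. A T cell list raised 2-fold in that simulation, where genes vary independently, had a camera adjusted p of 0.0012 and an exact permutation adjusted p of 0.0996 for its level, the smallest value possible when a single one of the 46 lists moves.

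Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma voom with quality weights, no filter and a filter at a mean CPM of 1, stricter thresholds, the replicate number as a block, each tumour left out, the skeletal muscle level as covariate, 1 surrogate variable from sva 3.50.0, camera with a preset correlation, and fry. Chosen after seeing the data were the removal of 3 libraries, the test of list levels with each tumour left out, the removal of ribosomal RNA and mitochondrial genes, bins of 10 Mb, and the lists of lymph node and imprinted genes. The labels name 1 batch, so no batch term was used. The library names carry lower numbers for every Tn tumour than for every WT tumour. What this order stands for is not stated, and an effect of it cannot be told apart from the group. All labelled samples were used.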

Results

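The series measured messenger RNA in 12 tumours grown in mice from 4T1 cells, a mouse mammary carcinoma line used as a model of triple-negative breast cancer. In 6 tumours the injected cells were parental (WT). In the other 6 the cells carried a CRISPR/Cas9 silencing of Cosmc, the gene C1galt1c1, whose product is the chaperone of the enzyme that extends O-linked glycans, so that the cells display the truncated Tn antigen (Tn). The labels call the 6 tumours of each group biological replicates. The tumours were chosen across sizes, and the size of each tumour is not in the labels used here. The table held 57186 genes, and the counts per tumour summed to between 113575859 and 156880766.

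Cosmc was measured first, as a check of the labels. C1galt1c1 (ENSMUSG00000048970, GRCm39 chromosome X, 37719662 to 37723964) was present at 19.6 ± 3.05 CPM in WT and 11.3 ± 0.775 CPM in Tn tumours (SD, n = 6 each). The 6 WT tumours held 16.4, 21.4, 23, 21.8, 19.6 and 15.5 CPM, and the 6 Tn tumours held 12.9, 11.2, 10.8, 11.2, 10.9 and 10.9 CPM. All 6 Tn tumours lay below every WT tumour. The log2 fold change was -0.80 ± 0.11 (SE; edgeR quasi-likelihood test, adjusted p = 0.000201), which left 57.6% of the WT level. An exact two-sided permutation test of the log2 CPM over all 924 assignments gave p = 0.00216, the smallest it can give. Total tumour tissue was sequenced, so the level sums injected cells and cells of the mouse.

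**Figure D1:**
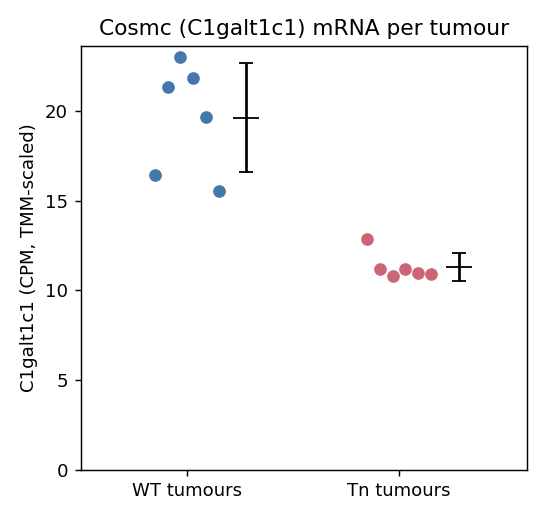
TMM-scaled C1galt1c1 CPM (vertical axis) in each tumour of the 2 groups, with the group mean and SD (n = 6 each) beside the points. The Tn tumours sit between 10.8 and 12.9 CPM, below the WT range of 15.5 to 23 CPM.

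The first principal component of log2 CPM held 38.1% of the variance and placed all 6 WT tumours on one side and all 6 Tn tumours on the other. The second held 16.4%, with WT tumour 1 and Tn tumour 4 at its ends. The third held 13%, with Tn tumour 6 at its end.

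The main comparison asked which genes differ between tumours of Cosmc-silenced and of parental cells. Of 19255 genes tested, 3752 rose and 3342 fell in Tn tumours (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 6 tumours each). Of these, 1079 rose and 1373 fell by at least 2-fold. The groups did not overlap in 3303 genes, 17.2% of those tested, where chance gives 0.216%. With upper-quartile scaling, 3094 rose and 3844 fell, so which direction holds more genes depends on the scaling. Of all 12 tumours, Tn tumour 4 held the highest level of the B cell list (7.00), Tn tumour 6 of the keratinocyte list (7.35) and WT tumour 6 of the adipocyte list (6.27, in log2 CPM). Results were also computed without these 3 libraries, a setting chosen after seeing the data, where the smallest p of the exact permutation test is 0.00794.

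The 10 largest falls were in genes with a mean below 1 CPM in Tn tumours. Adamtsl3, a secreted ADAMTS-like matrix protein (ENSMUSG00000070469, GRCm39 chromosome 7, 81984902 to 82263658), had 56.5 ± 13.2 CPM in WT and 0.324 ± 0.378 CPM in Tn tumours (SD, n = 6 each), a log2 fold change of -7.44 ± 0.64 (SE, edgeR adjusted p = 1.88e-05). Acsl6, an acyl-CoA synthetase, fell from 13.5 ± 1.43 to 0.333 ± 0.117 CPM (log2 fold change -5.34 ± 0.23, adjusted p = 7.22e-08). The other members of the 10 largest falls, with their log2 fold changes, were Nyap2 (-5.31), Oscar (-4.93), Dok7 (-4.85), Pgbd5 (-4.82), Lmo1 (-4.45), Mal (-4.43), Dmbt1 (-4.39) and Slc9b2 (-4.28). Except for Dmbt1, all 6 Tn tumours lay below all 6 WT tumours in each of these 10 genes. Dmbt1 had 0 CPM in WT tumour 1, and it did not pass without the 3 libraries, at -3.33 (edgeR adjusted p = 0.0732), with limma voom (adjusted p = 0.163) or with no filter (edgeR adjusted p = 0.0699).

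Among the 10 largest rises, Pitx1, a homeobox transcription factor (ENSMUSG00000021506, GRCm39 chromosome 13, 55972864 to 55984005), had 0.0142 ± 0.0248 CPM in WT and 2.09 ± 1.82 CPM in Tn tumours (SD, n = 6 each) and was higher in 6 of 6 Tn tumours (edgeR adjusted p = 0.000294). Of the other rises, Pou2af1, Cd79a, Pax5, Cd79b, Jchain, Tnfrsf13c and Cxcr5 are genes of B cells or plasma cells, Coch is a secreted protein, and Krt16 is a keratin of stressed skin. Their log2 fold changes ran from 5.41 for Krt16 to 6.94 for Pou2af1. The B cell genes were set by Tn tumour 4, where Cd79a reached 167 CPM against at most 1.67 CPM in the other Tn tumours. Without that tumour, 5 of the 10 rises no longer passed, namely Pou2af1 (0.50), Cd79a (1.47), Jchain (1.19), Coch (2.30) and Cxcr5 (-0.08), while Pax5 (1.61), Cd79b (1.16) and Tnfrsf13c (1.43) passed. Without the 3 libraries Cd79a, at 2.28 (edgeR adjusted p = 0.0164), and Pax5, at 1.88 (edgeR adjusted p = 0.0107), passed, Pou2af1, Jchain, Cxcr5, Cd79b, at 0.81 (edgeR adjusted p = 0.0504), and Tnfrsf13c, at 1.32 (edgeR adjusted p = 0.1), did not, and Coch was not tested. Krt16 was set by Tn tumour 6, at 552 CPM, and without that tumour its log2 fold change was -1.64 (edgeR adjusted p = 0.0216). Krt16 also did not pass without any single one of the WT tumours (edgeR adjusted p from 0.0754 to 0.09), Jchain without WT tumour 1, 2, 3 or 4, and Cxcr5 without WT tumour 1, 2, 3, 4 or 6. With limma voom, Pitx1 alone of these 10 genes passed.

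T cell and natural killer cell genes rose in Tn tumours. In the list of T cell and cytotoxicity genes, 22 of 25 tested members rose and 0 fell, against 22 and 0 adjusted over the list alone. Nkg7, a protein of cytotoxic granules, rose from 1.59 ± 0.963 to 16.2 ± 9.87 CPM. With log2 fold changes ± SE from edgeR, the T cell receptor component Cd3g (3.75 ± 0.58, adjusted p = 0.000524), the pore-forming perforin gene Prf1 (2.79 ± 0.45, adjusted p = 0.000708) and granzyme B, Gzmb (2.85 ± 0.48, adjusted p = 0.000925), rose as well. The level of the list rose from 0.12 ± 0.60 to 2.67 ± 1.10 log2 CPM (SD, n = 6 each; exact permutation test, adjusted p = 0.0124). Of the natural killer cell list, 10 rose and 0 fell of 10 (10 and 0 adjusted over the list alone), with Klrd1 (2.97), Xcl1 (2.15), Klre1 (2.80) and Fasl (3.03), and its level changed by 2.12 (exact permutation adjusted p = 0.0153). With an estimated correlation, camera gave adjusted p = 0.38 for the T cell list and adjusted p = 0.332 for the natural killer cell list. Without the 3 libraries the natural killer cell level differed by 1.83 (exact permutation adjusted p = 0.0644), which did not pass.

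Genes of antigen presentation and of the interferon response rose together. Of MHC class II presentation genes, 12 rose and 0 fell of 12 (12 and 0 adjusted over the list alone). H2-Eb1, H2-Aa and H2-Ab1, which encode class II chains, rose by 2.15, 2.05 and 2.01 on the log2 scale. Of MHC class I presentation genes, 20 rose and 0 fell of 22 (22 and 0 adjusted over the list alone), with the peptide transporter Tap2 (1.03 ± 0.12, adjusted p = 0.000102) and the immunoproteasome subunit Psmb8 (1.13 ± 0.18, adjusted p = 0.000619) from edgeR. Of type I interferon response genes, 22 rose and 0 fell of 29 (26 and 0 adjusted over the list alone), among them Bst2 (1.34), Ifi44 (1.28), Isg15 (0.93) and Ddx60 (0.98). The list levels changed by 2.07, 0.97 and 0.79, with exact permutation adjusted p = 0.0124, 0.0124 and 0.0153. With an estimated correlation, camera gave adjusted p = 0.362, 0.282 and 0.38.

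Macrophage genes rose, led by the complement genes C1qa (1.61), C1qb (1.66) and C1qc (1.63) and by Aif1 (1.74). In the macrophage list, 12 rose and 1 fell of 21 (14 and 1 adjusted over the list alone), and its level changed by 0.69 (exact permutation adjusted p = 0.0284). In the list of alternatively activated macrophage genes, 6 rose and 2 fell of 17 (7 and 2 adjusted over the list alone), with a level change of 0.83 (exact permutation adjusted p = 0.0166). Pdcd1lg2, a ligand of the checkpoint receptor PD-1, rose by 3.78, while Vegfa, a growth factor of vessels, fell by 0.63 on the log2 scale. Of inflammatory macrophage genes, 7 rose and 2 fell of 17 (9 and 2 adjusted over the list alone); the cytokine genes Il6 (-1.45) and Tnf (1.13) went opposite ways, and the level did not pass (exact permutation adjusted p = 0.0747). Of immune checkpoint genes, 8 rose and 1 fell of 19 (10 and 1 adjusted over the list alone), with Pdcd1 (3.09) and Ctla4 (2.48) and, lower, Vtcn1 (-3.12). Of regulatory T cell genes, 6 rose and 1 fell of 10 (7 and 1 adjusted over the list alone), with Ccr8 (2.50) and Tnfrsf18 (2.08) higher and Lrrc32 (-1.67) lower. The levels of these 2 lists changed by 0.73 and 1.06 (exact permutation adjusted p = 0.0199 and 0.0166). With an estimated correlation, camera gave adjusted p = 0.483 for macrophages, 0.483 for alternatively activated and 0.645 for inflammatory macrophage genes, 0.498 for checkpoints and 0.582 for regulatory T cells. Without the 3 libraries the macrophage, alternatively activated macrophage and regulatory T cell levels differed by 0.77 (exact permutation adjusted p = 0.083), 0.73 (exact permutation adjusted p = 0.0876) and 0.73 (exact permutation adjusted p = 0.0876), which did not pass. As medians over members the regulatory T cell level differed by 1.61 (exact permutation adjusted p = 0.0187), and without the 3 libraries Tnfrsf18 was at 1.22. The macrophage level did not pass as a median over members, at 0.71 (exact permutation adjusted p = 0.0848), and the inflammatory macrophage level passed without Tn tumour 5, at 0.75 (exact permutation adjusted p = 0.0258).

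The levels of the B cell and neutrophil lists depended on Tn tumour 4. Of B cell and plasma cell genes, 9 rose and 0 fell of 13 (11 and 0 adjusted over the list alone), among them Ighm (4.33, 2.13 without Tn tumour 4, and not past the threshold with limma voom, adjusted p = 0.0519) and Bank1 (4.35, and 1.70 without it), but the level did not pass (exact permutation adjusted p = 0.243; camera adjusted p = 0.754 with an estimated correlation). Without Tn tumour 4, in this list 5 rose and 2 fell, and the level differed by 0.45 (exact permutation adjusted p = 0.429). Of neutrophil genes, 4 rose and 2 fell of 25 (4 and 2 adjusted over the list alone), with Padi4 (1.00) and Lcn2 (1.71) higher and the gelatinase gene Mmp9 (-2.20) lower. With all tumours the neutrophil level differed by -0.64 while camera placed the list higher, and neither passed (exact permutation adjusted p = 0.164; adjusted p = 0.958 with an estimated correlation). Without Tn tumour 4, 4 rose and 10 fell and the neutrophil level passed, at -0.93 (exact permutation adjusted p = 0.0346), as it did without the 3 libraries, at -0.97 (exact permutation adjusted p = 0.0487). Of dendritic cell genes, 8 rose and 1 fell of 20 (11 and 1 adjusted over the list alone), and of mast cell and eosinophil genes, 6 rose and 1 fell of 13 (8 and 2 adjusted over the list alone), with Mcpt1 (3.82, and 2.46 without Tn tumour 5) higher and the eosinophil chemokine receptor Ccr3 (-2.98) lower. Their levels did not pass (exact permutation adjusted p = 0.111 and 0.164; adjusted p = 0.498 and 0.763 with an estimated correlation), and the dendritic cell level depended on the tumours used: it passed without Tn tumour 5, at 0.85 (exact permutation adjusted p = 0.021), and was lower without Tn tumour 4, at 0.41 (exact permutation adjusted p = 0.17), and without the 3 libraries, at 0.32 (exact permutation adjusted p = 0.329).

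Chemokine genes moved in both directions. Of chemokine and receptor genes, 12 rose and 2 fell of 34 (14 and 2 adjusted over the list alone), with Cx3cl1 (1.45), Ccl4 (1.78) and Cxcr6 (2.32) higher and Cxcl14 (-1.79) lower, and a level change of 0.53 (exact permutation adjusted p = 0.0421; adjusted p = 0.483 with an estimated correlation). The chemokine call ended with 9 of the 12 tumours left out in turn, at an exact permutation adjusted p of up to 0.0809, and with RLE scaling, at 0.52 (exact permutation adjusted p = 0.0516), as a median over members, at 0.56 (exact permutation adjusted p = 0.143), and without the 3 libraries, at 0.42 (exact permutation adjusted p = 0.143). Of myeloid cytokine genes, 7 rose and 3 fell of 22 (8 and 4 adjusted over the list alone), with Csf2 (1.53) higher and Lif (-0.73) and Il11 (-1.09) lower (exact permutation adjusted p = 0.0549; adjusted p = 0.68 with an estimated correlation), and this level passed without WT tumour 2, at 0.24 (exact permutation adjusted p = 0.0181), or WT tumour 5, at 0.21 (exact permutation adjusted p = 0.0476). Of complement genes, 6 rose and 2 fell of 20 (6 and 2 adjusted over the list alone) (exact permutation adjusted p = 0.584; adjusted p = 0.68 with an estimated correlation).

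Genes of the extracellular matrix and of stromal cells fell in Tn tumours. In the list of collagens and matrix proteins, 1 of 32 tested members rose and 25 fell, against 1 and 25 adjusted over the list alone. Tenascin C, encoded by Tnc, fell from 2034 ± 209 to 407 ± 127 CPM. By edgeR, with log2 fold change ± SE, Col12a1 (-1.66 ± 0.14, adjusted p = 1.41e-05), Vcan (-2.30 ± 0.20, adjusted p = 1.63e-05) and Thbs2 (-1.58 ± 0.14, adjusted p = 2.3e-05) fell with it. The level of the list fell from 8.98 ± 0.22 to 7.67 ± 0.19 log2 CPM (SD, n = 6 each; exact permutation adjusted p = 0.0124). Of fibroblast genes, 1 rose and 16 fell of 22 (1 and 16 adjusted over the list alone), with Lrrc15 (-2.08), Postn (-1.44) and Lum (-1.65). Of pericyte and smooth muscle genes, 0 rose and 11 fell of 15 (0 and 11 adjusted over the list alone), with Cnn1 (-2.66), Acta2 (-1.81) and Cspg4 (-1.80). Of endothelial and angiogenesis genes, 0 rose and 15 fell of 27 (0 and 16 adjusted over the list alone), with Aplnr (-2.66) and Kdr (-1.14), the latter a receptor of Vegfa. Their levels changed by -1.20, -1.23 and -0.68 (exact permutation adjusted p = 0.0153, 0.0153 and 0.0199). With an estimated correlation, camera gave adjusted p = 0.125 for matrix, 0.199 for fibroblasts, 0.38 for pericytes and 0.483 for endothelium. Without the 3 libraries the endothelium level differed by -0.62 (exact permutation adjusted p = 0.0769), which did not pass.

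Invasion and mesenchymal genes fell with the matrix. Of metalloproteinase and invasion genes, 2 rose and 16 fell of 25 (2 and 16 adjusted over the list alone), with Ctsk (-3.64), Mmp10 (-2.20) and Adam12 (-2.15). Of epithelial-mesenchymal transition genes, 1 rose and 11 fell of 20 (2 and 11 adjusted over the list alone), with Sparc (-1.28) and Prrx1 (-1.52), which fibroblasts also express. Of mammary tumour epithelium genes, 1 rose and 8 fell of 24 (1 and 8 adjusted over the list alone), with Prom2 (-3.02), Grhl2 (-1.31) and Cldn3 (-2.07). Grhl2 and Cldn3 are epithelial genes, and they fell along with the mesenchymal ones. The levels changed by -0.89, -0.70 and -0.91 (exact permutation adjusted p = 0.0124, 0.0124 and 0.0373). With an estimated correlation, camera gave adjusted p = 0.251, 0.199 and 0.523. The mammary epithelium call ended with 7 of the 12 tumours left out in turn, at an exact permutation adjusted p of up to 0.0676, and without the 3 libraries, at -0.89 (exact permutation adjusted p = 0.083).

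**Figure D2:**
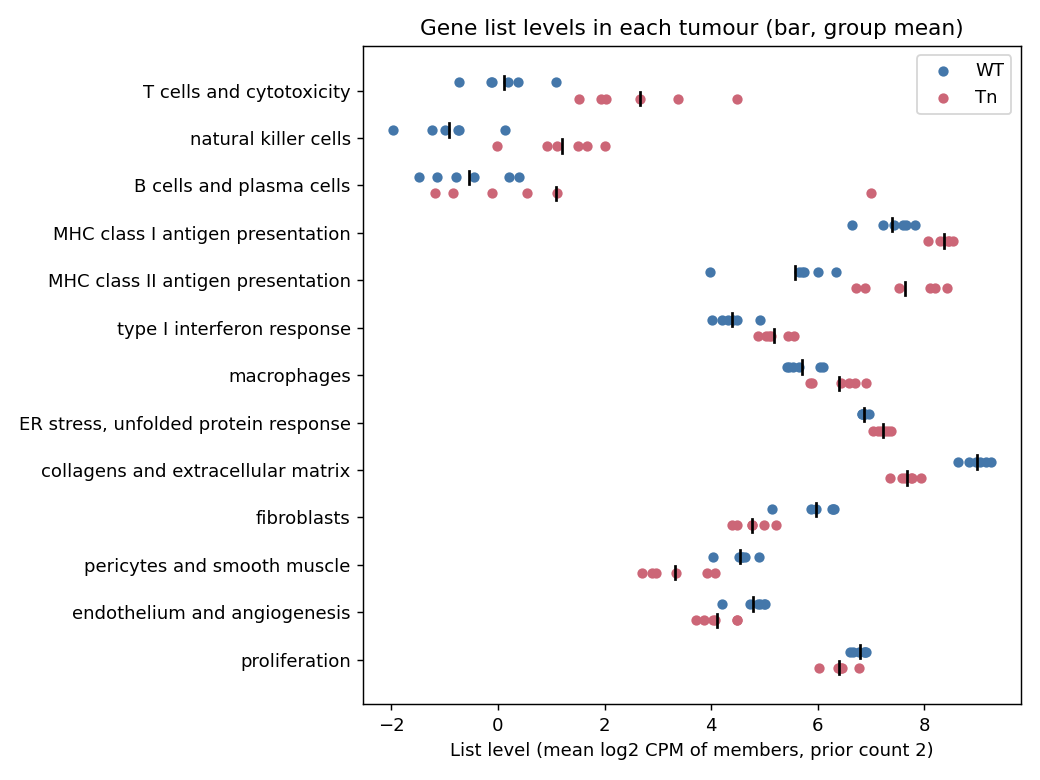
Level of selected gene lists (horizontal axis, mean log2 CPM of the members) in each WT and Tn tumour, with a bar at each group mean (n = 6 each). The matrix list lies at 8.98 in WT and 7.67 in Tn tumours, and the single high B cell point is Tn tumour 4.

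Enzymes of O-glycan synthesis moved in both directions. Of this list, which holds C1galt1c1 itself, 9 rose and 5 fell of 28 (9 and 8 adjusted over the list alone). Gcnt1, which builds core 2 O-glycans, rose from 5.35 ± 1.7 to 19.5 ± 4.99 CPM. Among the GalNAc transferases that start O-glycans, Galnt12 rose (0.81) and Galnt10 fell (-0.78). The mean level of the list differed by -0.10, its median fold change was 0.09, and neither test passed (exact permutation adjusted p = 0.119; adjusted p = 0.772 with an estimated correlation). The level passed without WT tumour 1, at -0.20 (exact permutation adjusted p = 0.0142), Tn tumour 1, at -0.18 (exact permutation adjusted p = 0.0498), or Tn tumour 4, at -0.20 (exact permutation adjusted p = 0.0234). Of mucin-type carrier genes, 1 rose and 7 fell of 15 (1 and 7 adjusted over the list alone), with Muc1 (-2.10) and Cd24a (-0.61) lower and Selplg (1.23) higher (exact permutation adjusted p = 0.0549; adjusted p = 0.483 with an estimated correlation), and their level passed without WT tumour 1, at -0.61 (exact permutation adjusted p = 0.0166). Of glycan-binding lectin genes, 10 rose and 1 fell of 19 (10 and 1 adjusted over the list alone). Mgl2, a macrophage lectin that binds terminal GalNAc, rose from 7.47 ± 4.68 to 66.5 ± 17.3 CPM (edgeR log2 fold change 3.15 ± 0.34, adjusted p = 6.43e-05). Clec7a (1.70) also rose. The lectin level changed by 0.65 (exact permutation adjusted p = 0.0398; adjusted p = 0.459 with an estimated correlation). As a median over members the lectin level differed by 1.62 (exact permutation adjusted p = 0.0153). The lectin call ended with 8 of the 12 tumours left out in turn, at an exact permutation adjusted p of up to 0.0738, and without the 3 libraries, at 0.59 (exact permutation adjusted p = 0.112).

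Genes of endoplasmic reticulum stress and protein folding rose. In this list, 15 of 24 tested members rose and 0 fell, against 15 and 0 adjusted over the list alone. By edgeR, with log2 fold change ± SE, the disulfide isomerases Pdia4 (0.72 ± 0.08, adjusted p = 7.36e-05) and Pdia6 (0.79 ± 0.09, adjusted p = 7.48e-05) and the chaperone Calr (0.53 ± 0.08, adjusted p = 0.000324) rose, each in 6 of 6 Tn tumours above all WT tumours. The level changed by 0.35 (exact permutation adjusted p = 0.0124; camera adjusted p = 0.276 with an estimated correlation), and as a median over members by 0.19 (exact permutation adjusted p = 0.0407).

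Proliferation genes fell. Of these, 0 rose and 17 fell of 30 (0 and 19 adjusted over the list alone), with the cell cycle genes Mki67 (-0.82), Plk1 (-0.71) and Cdk1 (-0.66), and the level changed by -0.38 (exact permutation adjusted p = 0.0166; adjusted p = 0.483 with an estimated correlation). Without the 3 libraries, 0 rose and 11 fell, and the level differed by -0.28 (exact permutation adjusted p = 0.083), which did not pass. Of apoptosis genes, 11 rose and 2 fell of 21 (12 and 2 adjusted over the list alone), with Bid (0.57) and the inhibitor Bcl2 (0.58) higher and Xiap (-0.62) lower, and a level change of 0.30 (exact permutation adjusted p = 0.0124; adjusted p = 0.465 with an estimated correlation). Of p53 targets, 4 rose and 5 fell of 22 (4 and 5 adjusted over the list alone), with Fas (1.57) higher and Zmat3 (-0.47) lower (exact permutation adjusted p = 0.584; adjusted p = 0.958 with an estimated correlation). Of immediate early genes, 2 rose and 5 fell of 20 (2 and 5 adjusted over the list alone), with Klf4 (1.00) higher and Ier3 (-0.75) lower (exact permutation adjusted p = 0.286; adjusted p = 0.754 with an estimated correlation).

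The levels of the Wnt, Notch and hypoxia lists fell, and those of the metabolic lists did not pass. Of Wnt genes, 3 rose and 14 fell of 24 (4 and 14 adjusted over the list alone), with Notum (3.24), an extracellular inhibitor of Wnt ligands, and Lgr6 (2.05) higher and Nkd2 (-1.45) and Wnt11 (-2.06) lower. Of Notch genes, 3 rose and 5 fell of 19 (3 and 7 adjusted over the list alone), with the target genes Nrarp (-0.98) and Heyl (-1.79) lower. Of hypoxia genes, 1 rose and 7 fell of 22 (1 and 7 adjusted over the list alone), with Lox (-2.25) and Anln (-1.18) lower and Egln3 (1.05) higher. The levels changed by -0.60, -0.44 and -0.31 (exact permutation adjusted p = 0.0166, 0.0166 and 0.0362; adjusted p = 0.199, 0.483 and 0.595 with an estimated correlation). As a median over members the Wnt level differed by -0.98 (exact permutation adjusted p = 0.0124). The hypoxia call ended with 9 of the 12 tumours left out in turn, at an exact permutation adjusted p of up to 0.0697, and without the 3 libraries, at -0.21 (exact permutation adjusted p = 0.225), where the Notch level did not pass either, at -0.35 (exact permutation adjusted p = 0.0644). Of oxidative phosphorylation genes, 12 rose and 2 fell of 31 (13 and 2 adjusted over the list alone), with Ndufa4 (0.98) and Sdhc (0.58). Of lipid and cholesterol genes, 0 rose and 7 fell of 24 (0 and 7 adjusted over the list alone), with Nsdhl (-0.61) and Lss (-0.52). Of glycolysis genes, 3 rose and 0 fell of 20 (3 and 0 adjusted over the list alone), with Hk2 (0.70) and Slc16a1 (0.62). The levels of these last lists did not pass (exact permutation adjusted p = 0.0631, 0.0516 and 0.852; adjusted p = 0.655, 0.637 and 0.916 with an estimated correlation). The oxidative phosphorylation level passed without WT tumour 6, at 0.23 (exact permutation adjusted p = 0.0181), and the lipid level with RLE scaling, at -0.27 (exact permutation adjusted p = 0.046), and without WT tumour 1, at -0.30 (exact permutation adjusted p = 0.0421), or WT tumour 2, at -0.31 (exact permutation adjusted p = 0.0346).

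Lists of neighbouring tissue and of RNA quality were measured in the same way. Of peripheral nerve genes, 0 rose and 5 fell of 11 (0 and 5 adjusted over the list alone), with Mal (-4.43) and Ncam1 (-1.91), and the level changed by -1.45 (exact permutation adjusted p = 0.0153; adjusted p = 0.325 with an estimated correlation). Of mammary gland and milk genes, 2 rose and 6 fell of 11 (2 and 6 adjusted over the list alone), with the milk protein gene Csn3 (3.72) higher and Pgr (-2.74, and -1.76 without the 3 libraries) and Esr1 (-0.55) lower. Of skeletal muscle genes, 0 rose and 1 fell of 21 (0 and 0 adjusted over the list alone), with Eno3 at -0.50, a call that ended with 8 of the 12 tumours left out in turn (edgeR adjusted p up to 0.0804). Of adipocyte genes, 0 rose and 2 fell of 17 (0 and 1 adjusted over the list alone), with Lep (-3.00) and Pparg (-1.71), and Pparg did not pass without WT tumour 6, at -1.06 (edgeR adjusted p = 0.0638), without Tn tumour 1, 3 or 5 (edgeR adjusted p up to 0.0571) or without the 3 libraries, at -1.30 (edgeR adjusted p = 0.0572). Of keratinocyte genes, 1 rose and 0 fell of 9 (0 and 0 adjusted over the list alone), and of erythroid genes, 0 rose and 0 fell of 10 (0 and 0 adjusted over the list alone). The levels of the mammary gland, muscle, adipocyte, keratinocyte and erythroid lists did not pass (exact permutation adjusted p = 0.178, 0.852, 0.304, 0.859 and 0.103; adjusted p = 0.68, 0.916, 0.68, 0.903 and 0.68 with an estimated correlation). The adipocyte level passed without WT tumour 1, at -2.02 (exact permutation adjusted p = 0.0421), and was -0.68 (exact permutation adjusted p = 0.553) without WT tumour 6. Of mitochondrially encoded transcripts, 0 rose and 5 fell of 13 (0 and 5 adjusted over the list alone), with mt-Nd5 (-0.57) and mt-Co1 (-0.60) lower (exact permutation adjusted p = 0.0674; adjusted p = 0.637 with an estimated correlation), and their level passed without WT tumour 4, at -0.47 (exact permutation adjusted p = 0.0398), or Tn tumour 5, at -0.48 (exact permutation adjusted p = 0.0216). Without the 3 libraries mt-Nd5, at -0.37 (edgeR adjusted p = 0.129), and mt-Co1, at -0.42 (edgeR adjusted p = 0.149), did not pass. Of ribosomal protein genes, 13 rose and 0 fell of 30 (13 and 0 adjusted over the list alone), with Rpl11 (0.45), and the level changed by 0.18 (exact permutation adjusted p = 0.0373; adjusted p = 0.608 with an estimated correlation). The ribosomal protein call ended with 4 of the 12 tumours left out in turn, at an exact permutation adjusted p of up to 0.0676, as a median over members, at 0.17 (exact permutation adjusted p = 0.0766), and without the 3 libraries, at 0.18 (exact permutation adjusted p = 0.135). These genes have many processed copies, so their counts are uncertain.

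Across the 46 lists, the level per tumour differed in 26, of which 14 were higher and 12 lower in Tn tumours (exact permutation test, Benjamini-Hochberg over the lists). Of these calls 14 held in every setting of the level test that was run, 12 ended without the 3 libraries, and 5 of those also ended with single tumours left out. Another 10 lists passed only in some other setting. By camera with an estimated correlation, 0 lists passed and 7 had an unadjusted p under 0.05. With the preset correlation of 0.01 camera called 29, and fry, which tests whether a list moves one way and does not compare it with other genes, called 27. No call of camera with the preset correlation held with the estimated one.

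Changed genes were unevenly placed along the genome. On chromosome 10, 311 of 381 changed genes fell, 81.6% (Fisher's exact test against the other chromosomes, two-sided, adjusted p = 7.58e-45), and its median log2 fold change was -0.21. Each chromosome was given a level per tumour, the median over its genes of log2 CPM. The mean of each gene over all tumours was subtracted first. The level of chromosome 10 was lower in 6 of 6 Tn tumours than in every WT tumour (exact permutation adjusted p = 0.00866). The same full separation and p were found on chromosomes 5 and 16, lower in Tn tumours, and on chromosomes 4 and 8, higher. On chromosome 4, 28.6% of 455 changed genes fell, and on chromosome 1, 32.1% of 499 fell. These shares were compared after the data were seen. An excess of changed genes of either direction or a shortage passed on 8 chromosomes (Fisher's exact test, adjusted over chromosomes). In bins of 10 Mb, a view chosen after seeing the data, the median over protein-coding genes with a mean of at least 5 CPM was below 0 in all 13 bins of chromosome 10. It was above 0 in every bin of chromosome 6, from 0.038 to 0.56. On chromosome 19 it was 0.35 and 0.33 in the first 20 Mb and -0.26 from 50 to 60 Mb. In the bin from 30 to 40 Mb of the X chromosome, which holds C1galt1c1, it was -0.33 over 17 genes, so the fall of C1galt1c1 came in a stretch where other genes were lower as well.

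**Figure D3:**
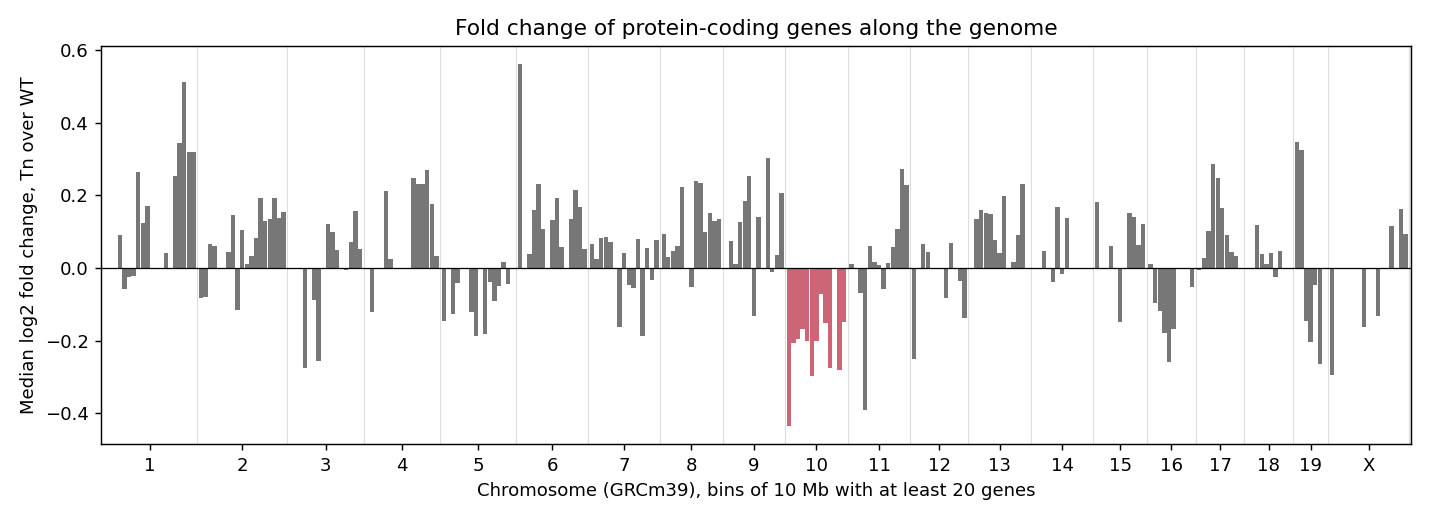
Median log2 fold change of protein-coding genes with a mean of at least 5 CPM (vertical axis) in bins of 10 Mb with at least 20 genes along each chromosome (horizontal axis), with chromosome 10 in red. Its median over all tested genes was -0.21.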

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

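The tests of lymph node tissue and of the share of tumour cells were chosen after the result was seen, and the count of other splits before. A tumour was singled out where its gap to the nearest tumour of its group, as a ratio to the range of the group, was above the 95% critical value for 6 values. This was so in 29 of 308 groups of values, where chance gives about 1 in 20. For single genes the ratio was computed on log2 CPM, while the values printed beside it are CPM.

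Of 100 splits of the 12 tumours into 6 and 6, the real one included, 1 gave as many changed genes as the real split, which gave 7094. The highest of the other splits gave 12. So chance assignment of the tumours is argued against.

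Tn tumour 4 stood apart in B cell genes, whose list level was 7.00 against -1.18 to 1.10 (ratio 0.721) in the other Tn tumours. Among single genes it stood apart in Pou2af1 (122 against 0.0594 to 0.445 CPM, ratio 0.754), Cd79a (167 against 0.2 to 1.67 CPM, ratio 0.691), Pax5 (77.7 against 0.0891 to 0.66 CPM, ratio 0.718), Cd79b (147 against 0.448 to 1.29 CPM, ratio 0.82), Tnfrsf13c (38.7 against 0.169 to 0.771 CPM, ratio 0.729), Cxcr5 (44.7 against 0.048 to 0.246 CPM, ratio 0.784) and Hk2 (120 against 176 to 216 CPM, ratio 0.653). Tn tumour 6 stood apart in the keratinocyte list, at 7.35 against -0.55 to 1.61 (ratio 0.728), and in Krt16 (552 against 0.426 to 1.21 CPM, ratio 0.857).

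Lymphocyte genes were higher in Tn tumours, and lymph node tissue in Tn tumour 4 is a candidate explanation. A list of lymph node genes, written after the data were seen, holds Cxcr5 and Coch, both among the 10 largest rises. A gap in this list was therefore partly built in. In it, Tn tumour 4 lay 4.11 log2 units above the highest other tumour. Without it, the T cell list was still higher by 2.20 (exact permutation p = 0.00216), so such tissue is not the whole source of the T cell rise. Of 13 B cell genes 5 still rose without it, more than the limit set for this explanation, but the B cell list level then differed by only 0.45 (exact permutation adjusted p = 0.429), so most of the B cell difference lay in this tumour. A lower share of tumour cells may raise all other cell types, but the T cell level less the endothelium level was higher in Tn tumours by 3.23 (exact permutation p = 0.00216), with endothelium at -0.68, so such a share is argued against as the whole cause. The mammary tumour epithelium level was lower as well, by 0.91 (exact permutation adjusted p = 0.0373), though this call ended with 7 of the 12 tumours left out in turn. Camera with an estimated correlation did not call this list (adjusted p = 0.523). So a lower share beside other changes, a response of the host to Cosmc-silenced cells and a difference in tumour size remain open.

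WT tumour 6 stood apart in the MHC class II list, at 3.98 against 5.66 to 6.34 (ratio 0.71), and in Pdcd1 (0.175 against 1.17 to 2.95 CPM, ratio 0.666), H2-Eb1 (66.5 against 212 to 409 CPM, ratio 0.639) and Nkd2 (20.9 against 13.5 to 15.8 CPM, ratio 0.634). WT tumour 1 stood apart in the endothelium list, at 4.21 against 4.74 to 5.00 (ratio 0.666), and in Dmbt1 (0 against 3.7 to 41.4 CPM, ratio 0.695), Calr (789 against 916 to 991 CPM, ratio 0.654), Cxcl14 (454 against 539 to 575 CPM, ratio 0.724) and Lep (0.214 against 4.04 to 20.6 CPM, ratio 0.638). WT tumour 2 stood apart in Mal (0.434 against 2.5 to 6.49 CPM, ratio 0.644), Mgl2 (16.9 against 4.33 to 6.79 CPM, ratio 0.67), Lrrc15 (278 against 175 to 206 CPM, ratio 0.645), Col12a1 (1687 against 1066 to 1202 CPM, ratio 0.739) and Slc16a1 (292 against 224 to 237 CPM, ratio 0.78). Tn tumour 5 stood apart in the epithelial-mesenchymal list, at 7.16 against 6.76 to 6.85 (ratio 0.778), and in mt-Nd4l (0.328 against 0.139 to 0.193 CPM, ratio 0.627). Tn tumour 2 stood apart in Pdcd1lg2 (31.7 against 6.86 to 9.64 CPM, ratio 0.778), and Tn tumour 1 in C1galt1c1 (12.9 against 10.8 to 11.2 CPM, ratio 0.785). In WT tumour 4 the 10 most abundant genes took 5.15% of the counts, against 5.47% to 5.65% in the other WT tumours (ratio 0.64).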

How the results depend on the processing

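Removing the 3 libraries or ribosomal RNA and mitochondrial genes, the alternatives of the chromosome counts and components, and leaving tumours out for list levels were chosen after seeing the data. Changed genes numbered 7052 with RLE, 6938 with upper-quartile scaling (3094 higher, 3844 lower, 44.6% higher against 52.9%), 7880 with DESeq2, 7820 with limma voom, 6105 with no filter, 5918 at a mean CPM of 1, 7258 with the muscle level as covariate, 7238 with 1 surrogate variable and 6104 without the 3 libraries. Leaving out each tumour gave 6131 to 7061. By construction, stricter thresholds lowered the count, to 4025 (2109 higher, 1916 lower) at an adjusted p under 0.01 and to 2452 (1079 higher, 1373 lower) at 2-fold or more, where Cosmc, at -0.80, is not counted. Cosmc otherwise kept its direction and its side of the threshold, at -0.85 to -0.74 with each tumour left out.

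With the replicate number as a block, 5876 genes changed, 2998 higher and 2878 lower, and Cosmc was at -0.78. Named genes that no longer passed with the block included Lep, at -2.39 (edgeR adjusted p = 0.101), and Pgr, at -2.14 (edgeR adjusted p = 0.0782). Dmbt1 (edgeR adjusted p = 0.0922), Ighm (edgeR adjusted p = 0.159) and Bank1 (edgeR adjusted p = 0.119) did not pass with it either. Deviations of same-numbered tumours correlated at 0.10, 0.16, -0.12, -0.10, -0.08 and 0.14. Each WT tumour correlated most with a Tn tumour of another number, at 0.16 to 0.24. So no strong pairing by number was seen, but these values cannot exclude a weak one, and the labels do not say. No list passed camera with the block.

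Camera called 29 lists with a preset correlation and fry 27, against 0 with an estimated correlation. It called 0 to 3 with each tumour left out: fibroblasts, matrix and Wnt genes without WT tumour 1, and epithelial-mesenchymal, matrix and metalloproteinase genes without Tn tumour 5. List levels that differed numbered 15 without the 3 libraries, against 26, where fewer tumours also raise the smallest p, and 22 to 28 with each tumour left out. Chromosomes with an excess or shortage of changed genes numbered 3 with upper-quartile scaling, 3 with limma voom, 4 at a mean CPM of 1 and 16 for the share that fell, against 8 in the main comparison; the cause was not tested.

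Of 189 named genes, 4 changed sign. Krt16, Krt6a and Krt17 were at -0.51, -1.61 and -1.09 with limma voom, -0.55, -1.58 and -0.67 with the block, and -1.52, -3.86 and -1.52 without the 3 libraries. With each tumour left out they ran from -1.64 to 5.68, -4.54 to 5.05 and -1.91 to 2.76, lowest without Tn tumour 6. Cxcr5 was at -0.16 without the 3 libraries and ran from -0.0849 (without Tn tumour 4) to 5.98 with each tumour left out. The p53 level was -0.0538 as a median, and the keratinocyte level -0.29 without the 3 libraries. With each tumour left out, the levels of glycolysis ran from -0.0156 to 0.10, of skeletal muscle from -0.24 to 0.68 and of keratinocytes from -0.89 to 0.86; none of these passed. The cause was not tested.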

Other observations

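Imprinted transcripts that are expressed from the paternal allele fell in Tn tumours, a list written after the values were seen. Of 21 tested members, 14 fell and 1 rose. Kcnq1ot1 fell from 6.63 ± 4.06 to 0.368 ± 0.157 CPM and Airn from 3.83 ± 1.82 to 0.232 ± 0.105 CPM (SD, n = 6 each). Snrpn (-3.50), Peg10 (-2.92) and Plagl1 (-2.23) fell too. Of 24 maternally expressed members, 10 fell, among them Meg3 (-2.39) and Grb10 (-1.49), and 3 rose, with H19 at 3.98. The level of the maternal list differed by -0.47 (exact permutation p = 0.00649), and that of the paternal list by -1.59 (exact permutation p = 0.00216). Dlk1, a paternally expressed member close to Meg3 on chromosome 12, fell as Meg3 did (-2.02). H19 ran from 135 to 3362 CPM in Tn tumours and from 13.7 to 172 CPM in WT tumours, so the groups overlapped. Airn and Kcnq1ot1 lie antisense to other genes, and the counts do not use the strand.

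These tests were chosen only after the fall of the list was seen, and the peripheral nerve comparison and the single loci after the other tests. Fewer fibroblasts may lower these transcripts: the list level less the fibroblast level differed by -0.38 (exact permutation p = 0.013), which had been set as evidence against this, a wrong limit, since the list was written after its fall was seen and the peripheral nerve list fell almost as far (difference -0.14, exact permutation p = 0.541), so a loss of stromal cells and a change within cells cannot be told apart. Loss of copies as the cause at all loci was argued against, since 172 other genes within 1 Mb of the 14 members that fell had a median of -0.0272 (95% bootstrap interval -0.16 to 0.03). It stays open from Snrpn to Peg12 on chromosome 7. There the 6 neighbours of Snrpn had a median of -0.37 (95% bootstrap interval -4.19 to -0.12). The single neighbour of Peg12 was at -1.36, and Ndn and Mkrn3 had none. The neighbours of Plagl1 were at -0.21. Loss at Airn, Sgce, Peg10 or Nap1l5 was not decided either, since the intervals of their neighbours were wide. These ran from -0.84 to 0.01 for Airn, -1.20 to 1.23 for Sgce and Peg10, and -1.01 to 0.67 for Nap1l5. A difference in imprinting or a change with Cosmc itself remains open, though maternally and paternally expressed members both fell.

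Changed genes leaned one way over whole stretches of chromosomes, with chromosome 10 lower along its length and chromosome 6 higher along its own. The window test was fixed before the data were seen, while the tests on chromosome 10 and on immune genes were chosen only after the result was seen, with predictions written before the test values. GC content and gene length, whose trend had an r squared of 0.892% over all genes, were argued against as the whole cause, since the median of chromosome 10 was -0.18 after their trend was removed (95% bootstrap interval -0.21 to -0.15) and -0.21 before. By the limit set for it, a different mixture of cells as the whole cause was argued against by genes of basic machinery. Their median was -0.07 on chromosome 10, with 8 genes below 0, and 0.17 elsewhere, a difference of -0.24 (13 genes, permutation p = 0.0048 over 10000 random sets). A wider set of families, computed before the set that the prediction named, gave -0.25 (22 genes, permutation p = 3e-04). These random sets treat genes as independent and do not cover the spread between tumours. Chromosome 10 was also chosen for its low values, so part of the difference may be built in, and a different mixture is not excluded.

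A clonal difference in copy number between the edited and the parental cells may move neighbouring genes together, but the test set for it leaves this open. The highest mean over 25 neighbouring genes, 1.69 against 0.91 with shuffled gene order, lay in the immunoglobulin region, with 9 immune genes. The highest median without listed immune genes, 0.93 against 0.70 shuffled, still held at least 9 immune or interferon-inducible genes such as Slamf8 and Ifi209. By the predictions as written, copy number would fit and immune clusters would not, but both windows were read as undecided after their genes were seen, since the exclusion had missed such genes. On chromosome 10 itself the median was -0.22 without immune genes (95% bootstrap interval -0.27 to -0.18). No DNA was measured.

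Genes chosen after their values were seen gave further values. Xist, the RNA that silences an X chromosome, had 4 counts in Tn tumour 4, or 0.0299 CPM without TMM scaling, against 31.2 to 96.5 in the other 11 tumours. The Y-linked genes Ddx3y and Eif2s3y had 12 and 14 counts in that tumour, only 0.0898 and 0.105 CPM without TMM scaling, and 0 in the other 11. Uty had 12 counts there and 1 in WT tumour 1, and Kdm5d had 4 there and 4 in Tn tumour 2. Whether Tn tumour 4 grew in an animal of the other sex was not tested, and every value that includes it carries this doubt. D17H6S56E-5 ran from 226 to 351 CPM in Tn tumours and from 1454 to 2090 in WT tumours. The 18S ribosomal RNA gene Rn18s-rs5 took 0.607% to 2.09% of counts in Tn tumours and 0.287% to 0.699% in WT tumours.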
